A study of Homo sapiens with 11 samples.

How the data were processed

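RNA sequencing of HuH7 cells, a human hepatocellular carcinoma line, was analysed in 11 libraries. Cells were transfected for 48 h with siRNA at 20 µM, per the labels, and RNA was isolated with a spin column kit. The groups are siSCR (4 libraries), siAKR1A1-1 (3) and siAKR1A1-2 (4), taken from the sample titles. The labels describe the cells both as a knockout and as an siRNA knockdown, and they are treated here as a knockdown because siRNA was transfected. The sequences of the siRNAs, the library kit and whether reads were counted by strand are not given in the sources used here, so reads of overlapping antisense genes cannot be separated. Nothing in the labels says that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

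Per the submitters' processing notes, the authors trimmed reads with cutadapt, checked them with FastQC, aligned them with STAR to GRCh38, counted them per gene with HTSeq and normalized the counts by relative log expression in DESeq2, with no versions given. The deposited values per library are on a log2 scale. They equal log2 of the normalized count plus 1, since turning them back gives means that match the mean signal per gene that the authors deposited beside them. The deposited tables also hold the authors' log2 fold change and p-value for each siRNA against siSCR. The siSCR values are identical in both tables, so a single normalization covers all libraries and the siRNAs could be compared directly. Turned back, the values of a library are whole multiples of what 1 read is worth: 100% were whole within a tolerance of 0.01 reads. The recovered reads gave 2063427 to 3849743 reads on genes per library. The tables list 33080 genes, 14348 of them with no read in any library.

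Because the deposited values are log2 normalized counts and not raw counts, the test set before the data were examined for such values was used: limma 3.58.1 in R 4.3.3 with a mean-variance trend on log2(value + 1). It was run on genes with a mean normalized count of at least 10 in the libraries compared, with Benjamini-Hochberg adjustment and a threshold of 0.05. Only the groups compared entered each fit. Every adjusted p for a gene comes from this test, two-sided, unless the authors' deposited table is named. A log2 fold change is the difference of mean log2(value + 1), which understates changes of low genes, and a fold is the ratio of mean normalized counts. Gene lists, 45 of them fixed before the data were examined, were tested with limma's camera at a preset correlation of 0.01 where at least 5 members were tested, leaving AKR1A1 out, with adjustment over lists. The same test with a correlation estimated per list gave 2 called lists for siAKR1A1-1 against siSCR (ribosome biogenesis and cytoskeleton genes) and 0 for the other comparisons.

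Genes named in the text follow a rule set before the data were examined. It takes AKR1A1, the 10 largest rises and falls per siRNA among called genes with a mean of at least 50 normalized counts and no overlap between the groups, the 10 genes per direction called in both comparisons whose smaller change was largest, and up to 4 members per list with the smallest adjusted p. Not every gene that the rule takes is reported here. Symbols are those of the deposited tables, some of them older names, and coordinates come from GENCODE release 29 on GRCh38.

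The 3' UTRs of the same annotation were searched for 7-mers with Python 3.11.15 in 9569 genes (94.5% of those tested in every comparison). Each of 16080 7-mers was scored by a z of the difference in log2 fold change between genes with and without it. This difference was adjusted for the length and GC content of the 3' UTR. The z was set against 100 scans with fold changes permuted over genes. On simulated data, a 7-mer given a log2 effect of -0.30 ranked first. Simulated libraries with known changes were made at the means and depth of the real ones. They had the same spread for all genes (dispersion 0.00908) and 200 changed genes, so rates in the real libraries may differ. On them the gene test was checked. It recovered 47.8%, 96.9% and 100% of changes of 1.5, 2 and 4-fold for siAKR1A1-1 against siSCR with 7 false calls among 10482 genes, 77.3%, 100% and 100% for siAKR1A1-2 against siSCR with 14, and 50%, 90.9% and 100% between the siRNAs with 6. Libraries of a group differed by more than sampling noise, with a chi-square per degree of freedom of 1.93 to 7.88, so no pair was treated as a library deposited more than once. This does not show whether they came from separate cultures. Alternatives tried were other filters, pseudocounts, thresholds and scalings, each library left out, all groups in a single fit, a block for the replicate number, split controls, and other tests of genes and lists. On the recovered reads, limma's voom called 3860, 2973 and 3348 genes for siAKR1A1-1 against siSCR, siAKR1A1-2 against siSCR and siAKR1A1-1 against siAKR1A1-2.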

Results

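RNA was sequenced from HuH7 cells, a human hepatocellular carcinoma line, after transfection with a scrambled control siRNA (siSCR, 4 libraries) or with an siRNA against AKR1A1. There were 2 of these, called siAKR1A1-1 (3 libraries, replicates 2 to 4) and siAKR1A1-2 (4 libraries). The depth behind the values was 2063427 to 3849743 reads on genes per siSCR library, 2161960 to 3358131 per siAKR1A1-1 library and 2169336 to 2929344 per siAKR1A1-2 library. The comparisons ask which transcripts differ between cells with the control siRNA and cells with reduced AKR1A1, and, since both siRNAs target the same gene, which of these changes they share. Mitochondrial transcripts took 2.75% ± 0.325 of the reads with siSCR (SD, n = 4), 4.24% ± 0.720 with siAKR1A1-1 (n = 3) and 3.20% ± 0.222 with siAKR1A1-2 (n = 4). On the third principal component of the log2 values (8.99% of the variance), siSCR replicate 4 had a score of -28.1 and the other siSCR libraries scores of 10.0 to 16.5. On it siAKR1A1-1 replicate 3 also lay apart from its group, at -17.0 against 10.5 and 5.68, while the siAKR1A1-2 libraries scored -5.09 to -1.25. Across genes, the deviations of siSCR replicate 4 and siAKR1A1-1 replicate 3 from their group means had a correlation of 0.473. Both had the fewest reads of their group (2063427 and 2161960). The siAKR1A1-2 library with the fewest reads, replicate 2 (2169336), scored -4.24, within the range of its group. Whether depth gives this component was not tested.

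AKR1A1 encodes an NADPH-dependent aldehyde reductase and lies on chromosome 1 at 45550543 to 45570049 in GRCh38 (GENCODE release 29) and is annotated as protein-coding. Its normalized read count was 295, 326, 304 and 397 in siSCR replicates 1 to 4, 25.6, 24.5 and 14.8 in siAKR1A1-1 replicates 2 to 4, and 102, 118, 104 and 68.8 in siAKR1A1-2 replicates 1 to 4. The mean fell 15.3-fold with siAKR1A1-1, from 330.5 ± 46.5 (SD, n = 4) to 21.6 ± 5.93 (n = 3; log2 fold change -3.90, SE 0.19, adjusted p = 2.42e-10). With siAKR1A1-2 it fell 3.37-fold, to 98.1 ± 20.8 (n = 4; log2 fold change -1.76, SE 0.15, adjusted p = 5.79e-08). AKR1A1 was lower with siAKR1A1-1 than with siAKR1A1-2 by a log2 difference of -2.14 (adjusted p = 2.69e-07). The authors' deposited table gives log2 fold changes of -3.67 and -1.64 for the siRNAs in the same order.

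**Figure D1:**
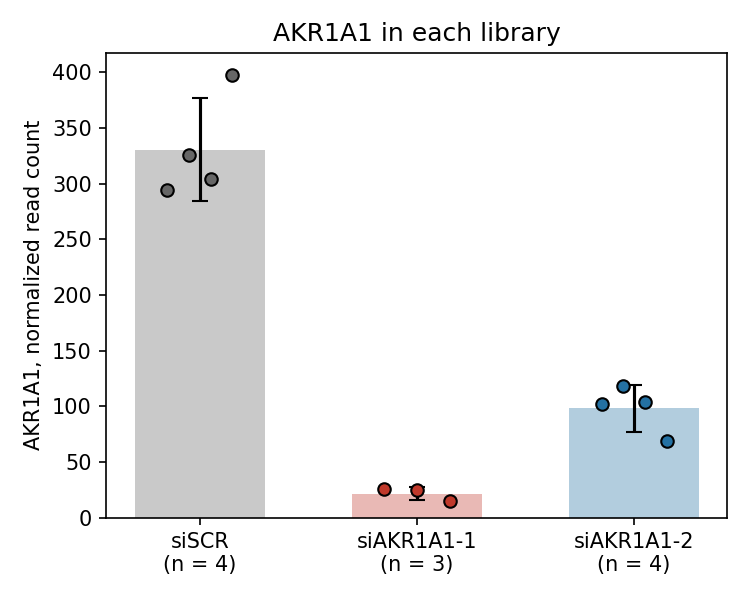
Normalized read count of AKR1A1 in each library, with bars at the group means and error bars of 1 SD. The siSCR libraries lie between 295 and 397, the siAKR1A1-2 libraries between 68.8 and 118, and the siAKR1A1-1 libraries between 14.8 and 25.6.

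With siAKR1A1-1, genes of the cytoskeleton were among the 10 largest rises. TUBA1A, an alpha-tubulin, rose 10.2-fold, from 77.8 ± 20.7 (SD, n = 4) to 791 ± 138 normalized counts (n = 3; adjusted p = 1.13e-09). ACTA1, the actin of skeletal muscle, rose 8.19-fold (adjusted p = 9.40e-10). SYT11, a synaptotagmin of vesicle trafficking, rose 9.16-fold (adjusted p = 2.45e-10). The 10 largest falls outside AKR1A1 included TFRC, the transferrin receptor that brings iron into cells, which dropped 13.4-fold from 411 ± 48.5 to 30.6 ± 7.51 (adjusted p = 2.35e-10). BECN1, the autophagy protein beclin, dropped 7.44-fold (adjusted p = 1.13e-09). SEC61A1, the channel of the endoplasmic reticulum translocon, dropped 5.75-fold from 713 ± 82.1 to 124 ± 9.26 (adjusted p = 2.42e-10). Further rises were seen for VGLL3, a cofactor of TEAD transcription factors (9.28-fold), CACNG4, a calcium channel subunit (8.96-fold), and FILIP1, a filamin-binding protein (8.53-fold). CYFIP2, part of the actin-regulating WAVE complex (7.69-fold), ROBO2, an axon guidance receptor (5.81-fold), and EPPK1, epiplakin (5.68-fold), also rose, all with adjusted p of at most 5.33e-07. Further falls were those of BRI3BP (6.74-fold), CYP1A1, a xenobiotic-metabolizing cytochrome P450 (6.48-fold), and KXD1 (6.38-fold). Others were FEM1A (6.17-fold), GDA, guanine deaminase (5.89-fold), RAB17, a GTPase of epithelial trafficking (5.66-fold), and the histone deacetylase HDAC3 (4.67-fold), with adjusted p of at most 3.03e-05. Without siAKR1A1-1 replicate 2 the fall of GDA was 9.01-fold.

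Ribosome biogenesis genes and targets of MYC fell together with siAKR1A1-1. In that list 26 of 31 genes fell and none rose over all genes tested, and 27 fell when adjusted over the list alone (camera adjusted p = 8.19e-11, and adjusted p = 0.0391 with an estimated correlation). SRM, spermidine synthase, fell 2.48-fold, and the nucleolar protein NOP56 fell 2.18-fold. In the list of epithelial-mesenchymal transition and cytoskeleton genes 15 of 21 rose and 2 fell, with 17 higher when adjusted over the list alone (camera adjusted p = 9.17e-07, and adjusted p = 0.0391 with an estimated correlation). Its members included TAGLN, an actin-binding protein of smooth muscle (4.38-fold, from 965 ± 78.3 to 4227 ± 336), TGFB2 (3.05-fold), SPARC (2.89-fold) and vimentin, VIM (2.06-fold). Targets of YAP and TEAD rose in 13 of 19 cases, 14 when adjusted over the list alone (camera adjusted p = 8.64e-06, and adjusted p = 0.164 with an estimated correlation). Among them were AMOTL2 (3.22-fold) and MYOF (3.37-fold). Genes of cholesterol synthesis and its regulator SREBP2 rose in 14 of 26 cases and 15 when adjusted over the list alone (camera adjusted p = 7.17e-06, and adjusted p = 0.130 with an estimated correlation). DHCR7, a reductase late in that pathway, rose 2.01-fold. Complement and coagulation genes rose in 10 of 22 cases, 12 when adjusted over the list alone (camera adjusted p = 0.00366, and adjusted p = 0.118 with an estimated correlation). SERPINF2 rose 1.95-fold and PROS1 2.46-fold.

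Heat shock genes fell in 12 of 19 cases with siAKR1A1-1, 15 when adjusted over the list alone (camera adjusted p = 2.27e-05, and adjusted p = 0.111 with an estimated correlation). The chaperone HSP90AA1 fell 2.09-fold and HSPH1 1.94-fold. Genes of the unfolded protein response fell in 11 of 23 cases, 12 when adjusted over the list alone (camera adjusted p = 0.0120, and adjusted p = 0.130 with an estimated correlation). The transcription factor XBP1 fell 1.86-fold and the chaperone HSPA5 1.56-fold. DNA replication genes fell in 14 of 40 cases and the same number when adjusted over the list alone (camera adjusted p = 5.11e-04, and adjusted p = 0.0794 with an estimated correlation). MCM3 fell 1.72-fold and RRM2 1.87-fold. Targets of NRF2, the regulator of antioxidant defence, fell in 13 of 24 cases and rose in 3, with 13 lower when adjusted over the list alone (camera adjusted p = 0.0422, and adjusted p = 0.174 with an estimated correlation). GCLM, which makes glutathione, fell 3.20-fold, TKT 2.44-fold and SLC7A11, the cystine importer, 2.63-fold. Without genes that carry any of 4 short 3' UTR sequences described for the direct comparison, the NRF2 list gave an adjusted p of 0.857, and leaving out siSCR replicate 1 or siAKR1A1-1 replicate 2 also ended its call (adjusted p up to 0.0691). Without the genes that carry those sequences or were not searched, the ribosome biogenesis and cytoskeleton lists, the only lists called with an estimated correlation, both had an adjusted p of 0.0538 with such a correlation. Mitochondrial transcripts rose in 9 of 13 cases and 9 when adjusted over the list alone (camera adjusted p = 5.11e-04, and adjusted p = 0.412 with an estimated correlation), beside a mitochondrial share of reads of 4.24%. Ribosomal protein genes fell in 15 of 54 cases and 15 when adjusted over the list alone (camera adjusted p = 0.00157, and adjusted p = 0.413 with an estimated correlation), and RPS28 fell 4.36-fold.

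In all, 3736 of 10483 genes tested passed an adjusted p of 0.05 with siAKR1A1-1, 1788 higher and 1948 lower, and 576 and 480 of these by at least 2-fold. With an adjusted p under 0.01 the count was 2356, and without genes that carry the short 3' UTR sequences or were not searched it was 2285. With values scaled to library totals, 2162 genes were higher and 1611 lower, so the larger side depends on the scaling. The libraries of the groups did not overlap for 40.3% of the genes, against 5.71% by chance. The authors' deposited table calls 3049 genes, 2964 of them changed in the same direction here. Of the 42 lists tested, 11 were called, 1 gene going the other way in each of the cholesterol, unfolded protein, complement and YAP lists, and 2 of the 35 splits of these 7 libraries, the real split included, called at least as many.

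With siAKR1A1-2, transcription factors of the early response to stimulation were among the 10 largest rises. KLF2 rose 3.14-fold, from 28.6 ± 5.68 (SD, n = 4) to 89.8 ± 24.3 normalized counts (n = 4; adjusted p = 1.21e-05). EGR1 rose 2.79-fold (adjusted p = 1.03e-06) and MAFF 2.76-fold (adjusted p = 2.43e-06). SLC43A2, an amino acid transporter, rose 3.26-fold, from 68.0 ± 9.59 to 222 ± 10.8 (adjusted p = 2.67e-08). TTN, which encodes the muscle protein titin, rose 3.10-fold (adjusted p = 1.13e-06). The 10 largest falls outside AKR1A1 included those of RPS19BP1, which dropped 5.18-fold from 194 ± 12.1 to 37.5 ± 8.28 (adjusted p = 5.63e-09). The actin capping subunit CAPZA2 dropped 4.49-fold (adjusted p = 6.38e-07), and DYNC1LI2, a light intermediate chain of dynein, 4.39-fold from 539 ± 66.2 to 123 ± 13.1 (adjusted p = 1.82e-10). PIP4K2C, a phosphoinositide kinase (2.95-fold), COTL1, an actin-binding protein (2.60-fold), TMEM140 (2.71-fold) and SPATA2 (2.60-fold) also rose, with adjusted p of at most 2.71e-04. Further falls were those of NABP2, a single-stranded DNA binding protein (3.91-fold), TOMM20, a receptor of mitochondrial protein import (3.68-fold), and LMAN2L (3.66-fold). Others were the splicing regulator MBNL1 (3.59-fold), SH2B1 (3.58-fold), DONSON, a DNA replication factor (3.55-fold), and FAM63B, now called MINDY2 (3.50-fold), with adjusted p of at most 7.19e-06.

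Immediate early genes rose in 15 of 24 cases with siAKR1A1-2, 16 when adjusted over the list alone (camera adjusted p = 6.42e-06, and adjusted p = 0.115 with an estimated correlation). Cholesterol synthesis genes rose in 15 of 26 cases and fell in 2, with 16 higher when adjusted over the list alone (camera adjusted p = 6.42e-06, and adjusted p = 0.0833 with an estimated correlation). DHCR7 rose 1.89-fold, while FDPS fell 1.85-fold. Targets of YAP and TEAD rose in 13 of 20 cases, 14 when adjusted over the list alone (camera adjusted p = 6.42e-06, and adjusted p = 0.0874 with an estimated correlation). AMOTL2 rose 1.91-fold and the kinase LATS2 2.12-fold. Cytoskeleton and mesenchymal genes rose in 13 of 21 cases, 15 when adjusted over the list alone (camera adjusted p = 9.03e-05, and adjusted p = 0.0833 with an estimated correlation). Fibronectin, FN1, rose 1.82-fold and TAGLN 1.74-fold. Autophagy and lysosome genes rose in 11 of 25 cases, 12 when adjusted over the list alone (camera adjusted p = 4.74e-04, and adjusted p = 0.0833 with an estimated correlation). The kinase ULK1 rose 1.99-fold and MAP1LC3B 1.86-fold. Targets of hypoxia rose in 9 of 20 cases, 9 when adjusted over the list alone (camera adjusted p = 0.00454, and adjusted p = 0.278 with an estimated correlation). NDRG1 rose 1.67-fold. Oncofetal liver genes rose in 8 of 20 cases, 10 when adjusted over the list alone (camera adjusted p = 0.00890, and adjusted p = 0.152 with an estimated correlation). Cholangiocyte and epithelial markers rose in 4 of 8, 4 when adjusted over the list alone (camera adjusted p = 0.0149, and adjusted p = 0.115 with an estimated correlation). SOX9, on both of these lists, rose 1.73-fold.

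Ribosome biogenesis genes and targets of MYC fell in 19 of 32 cases with siAKR1A1-2, 21 when adjusted over the list alone (camera adjusted p = 1.51e-07, and adjusted p = 0.0833 with an estimated correlation). Nucleolin, NCL, fell 2.54-fold from 7474 ± 566 to 2941 ± 156. Heat shock genes fell in 9 of 19 cases, 9 when adjusted over the list alone (camera adjusted p = 2.60e-04, and adjusted p = 0.0833 with an estimated correlation). HSPH1 fell 1.60-fold and HSPD1 1.43-fold. DNA replication genes fell in 9 of 40 cases, 9 when adjusted over the list alone (camera adjusted p = 0.0149, and adjusted p = 0.0874 with an estimated correlation). UNG, a uracil-DNA glycosylase, fell 2.99-fold and MCM3 1.57-fold, and without genes carrying the short 3' UTR sequences the list's adjusted p was 0.0738. Mitosis genes fell in 13 of 40 cases, 15 when adjusted over the list alone (camera adjusted p = 0.0310, and adjusted p = 0.115 with an estimated correlation). TOP2A fell 1.57-fold, while UBE2C rose 1.75-fold. Other aldo-keto reductases rose in 2 of 5 cases, 3 when adjusted over the list alone (camera adjusted p = 0.0290, and adjusted p = 0.134 with an estimated correlation), namely AKR1B1 (1.66-fold) and AKR1C1 (1.48-fold). Members of this family are similar in sequence and could share reads. Inflammation genes of the NF-kB pathway rose in 6 of 17 cases, 8 when adjusted over the list alone (camera adjusted p = 0.0290, and adjusted p = 0.121 with an estimated correlation). Mitochondrial transcripts rose in 5 of 13 cases and 5 when adjusted over the list alone (camera adjusted p = 0.0407, and adjusted p = 0.572 with an estimated correlation), beside a mitochondrial share of reads of 3.20%. Ribosomal protein genes fell in 12 of 54 cases, 10 when adjusted over the list alone (camera adjusted p = 0.0130, and adjusted p = 0.481 with an estimated correlation). Replication-dependent histone genes fell in 3 of 14, 3 when adjusted over the list alone (camera adjusted p = 0.0407, and adjusted p = 0.267 with an estimated correlation). Without siSCR replicate 3 the adjusted p was 0.220 for mitochondrial transcripts, 0.0906 for ribosomal proteins and 0.0735 for mitosis genes, and without siSCR replicate 4 it was 0.115 for histones. The mitochondrial list was also lost without siAKR1A1-2 replicate 1, 2 or 3, the histone list without siSCR replicate 1 or siAKR1A1-2 replicate 2 or 3, and the aldo-keto reductase list when genes with low counts were kept. Without genes that carry the short 3' UTR sequences or were not searched, the hypoxia list had an adjusted p of 0.0516 and the NF-kB list 0.0516, and too few aldo-keto reductase and mitochondrial genes were left to test.

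Over all genes, 2959 of 10322 tested passed with siAKR1A1-2, 1479 higher and 1480 lower, and 202 and 218 of these by at least 2-fold. With a fold change of at least 1.5 also required, the count was 1539, with an adjusted p under 0.01 it was 1687, and without genes that carry the short 3' UTR sequences or were not searched it was 1914. In the DNA replication, NF-kB, oncofetal, cytoskeleton and autophagy lists 1 gene each went the other way. The groups did not overlap for 27.9% of the genes, against 2.86% by chance. The authors' deposited table calls 2308 genes, of which 2262 changed in the same direction here.

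**Figure D2:**
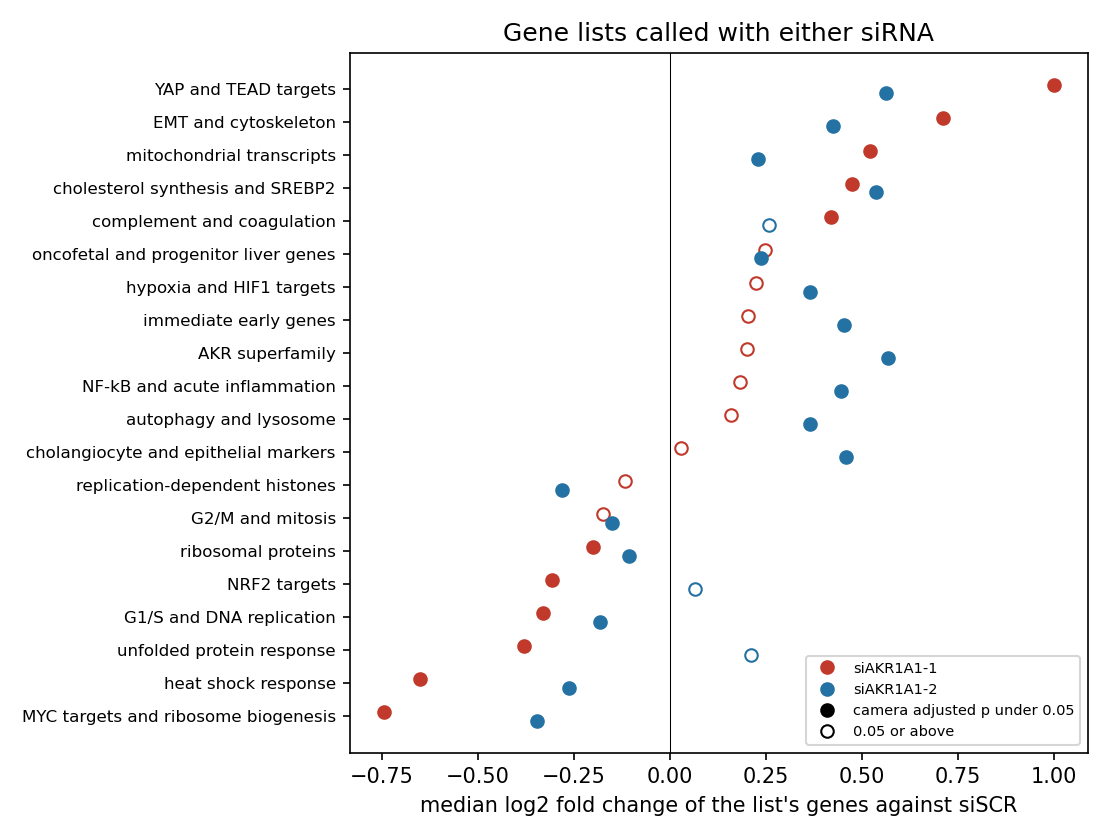
Median log2 fold change against siSCR of the genes in each list called with at least 1 of the siRNAs (red, siAKR1A1-1; blue, siAKR1A1-2), filled where the camera adjusted p was under 0.05. The 8 lists called with both siRNAs, against the same siSCR libraries, have the same direction, while with an estimated correlation 2 lists were called with siAKR1A1-1 and 0 with siAKR1A1-2, and with siAKR1A1-1 the aldo-keto reductase, NF-kB and immediate early lists have medians above 0 and means below 0.

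Set directly against each other, the siRNAs left TFRC, SEC61A1 and RPS28 at lower levels with siAKR1A1-1. TFRC was at 30.6 ± 7.51 normalized counts with siAKR1A1-1 (SD, n = 3) and 417 ± 54.7 with siAKR1A1-2 (n = 4; log2 difference -3.74, SE 0.16, adjusted p = 5.63e-14). SEC61A1 was at 124 ± 9.26 and 773 ± 40.1 (adjusted p = 3.35e-14), and RPS28 at 539 ± 30.9 and 2606 ± 193 (adjusted p = 3.35e-14). Of the 166 genes that moved in opposite directions from siSCR, 91 fell with siAKR1A1-1 and rose with siAKR1A1-2, and 75 went the other way. The examples were singled out after their values were seen. DUSP5, a phosphatase that acts on ERK kinases, fell 4.37-fold with siAKR1A1-1 and rose 1.42-fold with siAKR1A1-2 (log2 difference -2.62, adjusted p = 4.85e-14). EGR1 fell 4.83-fold and rose 2.79-fold (log2 difference -3.62, adjusted p = 2.38e-11). The same held for NDRG1 (-1.90), SLC7A11 (-1.97), AKR1C1 (-1.83), NQO1, a quinone reductase (-1.26), and CALR, the chaperone calreticulin (-1.28), given as log2 differences with adjusted p of at most 4.39e-09. In the other direction, SLC7A5, an amino acid transporter, rose 2.12-fold with siAKR1A1-1 and fell 1.63-fold with siAKR1A1-2 (log2 difference 1.78, adjusted p = 3.11e-10). RPS19BP1 (log2 difference 2.03), DYNC1LI2 (1.98) and LMAN2L (2.08) were higher with siAKR1A1-1. Genes of the unfolded protein response were a list lower with siAKR1A1-1 (13 of 22 genes lower, 13 when adjusted over the list alone, camera adjusted p = 2.85e-04, and adjusted p = 0.183 with an estimated correlation). So were ribosome biogenesis genes (12 of 32, 14 adjusted over the list alone, camera adjusted p = 0.00948, and adjusted p = 0.203 with an estimated correlation) and NRF2 targets (11 of 24, 12 adjusted over the list alone, with 2 higher, camera adjusted p = 0.00948, and adjusted p = 0.203 with an estimated correlation). The same direction held for heat shock genes (12 of 19, 12 adjusted over the list alone, camera adjusted p = 0.0318, and adjusted p = 0.349 with an estimated correlation). Immediate early genes went both ways, 10 of 24 lower and 6 higher, or 10 and 8 adjusted over the list alone, with the list lower on balance (camera adjusted p = 0.0425, and adjusted p = 0.474 with an estimated correlation). Also lower were aldo-keto reductases (3 of 5, 3 adjusted over the list alone, camera adjusted p = 0.0318, and adjusted p = 0.368 with an estimated correlation). Mitochondrial transcripts were higher with siAKR1A1-1 in 6 of 13 cases (7 adjusted over the list alone, camera adjusted p = 0.00948, and adjusted p = 0.507 with an estimated correlation). Cytoskeleton genes were higher in 8 of 21 and lower in 3 (8 higher adjusted over the list alone, camera adjusted p = 0.0300, and adjusted p = 0.368 with an estimated correlation) and complement genes in 7 of 21 (7 adjusted over the list alone, camera adjusted p = 0.0318, and adjusted p = 0.368 with an estimated correlation). In the heat shock and ribosome biogenesis lists 1 gene each was higher. Without genes carrying the short 3' UTR sequences, the adjusted p was 0.728, 0.276 and 0.0639 for NRF2 targets, immediate early and complement genes, and too few mitochondrial and aldo-keto reductase genes were left to test.

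Genes with particular 7-base sequences in the 3' untranslated region (3' UTR) differed from the rest. In 9569 genes with an annotated 3' UTR, the 7-mers that went with the lowest values in siAKR1A1-1 relative to siAKR1A1-2 were CTGAGAT and TGAGATA. Those that went with the lowest values in siAKR1A1-2 were CAGTTAC and AGTTACA, both pairs chosen from these values by a scan of 16080 7-mers. Either of the first pair was present in 21.5% of all these genes, in 31.1% of those lower with siAKR1A1-1 than with siSCR and in 60% of the 50 with the lowest log2 fold change. Either of the second pair was present in 15.9% of all genes, in 23.0% of those lower with siAKR1A1-2 and in 58% of the 50 lowest. These shares were not adjusted for the length or GC content of the 3' UTR. Of the 10 largest falls named for siAKR1A1-1, 7 carried a 7-mer of the first pair, among them TFRC, BECN1, KXD1, RAB17 and HDAC3. The other 3 (SEC61A1, GDA and CYP1A1) did not. Of the 10 named for siAKR1A1-2, 9 carried a 7-mer of the second pair and LMAN2L did not. GCLM, TKT, SLC7A11 and RPS28 also carried a 7-mer of the first pair. Between the siRNAs, 3289 of 10456 genes tested passed, 1556 higher and 1733 lower with siAKR1A1-1, and 1854 when genes carrying any of the 4 7-mers or with no searched 3' UTR were left out. With an adjusted p under 0.01 the count was 2156, and with a fold of at least 1.5 it was 2102. With values scaled to library totals, 1839 were higher and 1477 lower, which turns the larger side.

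**Figure D3:**
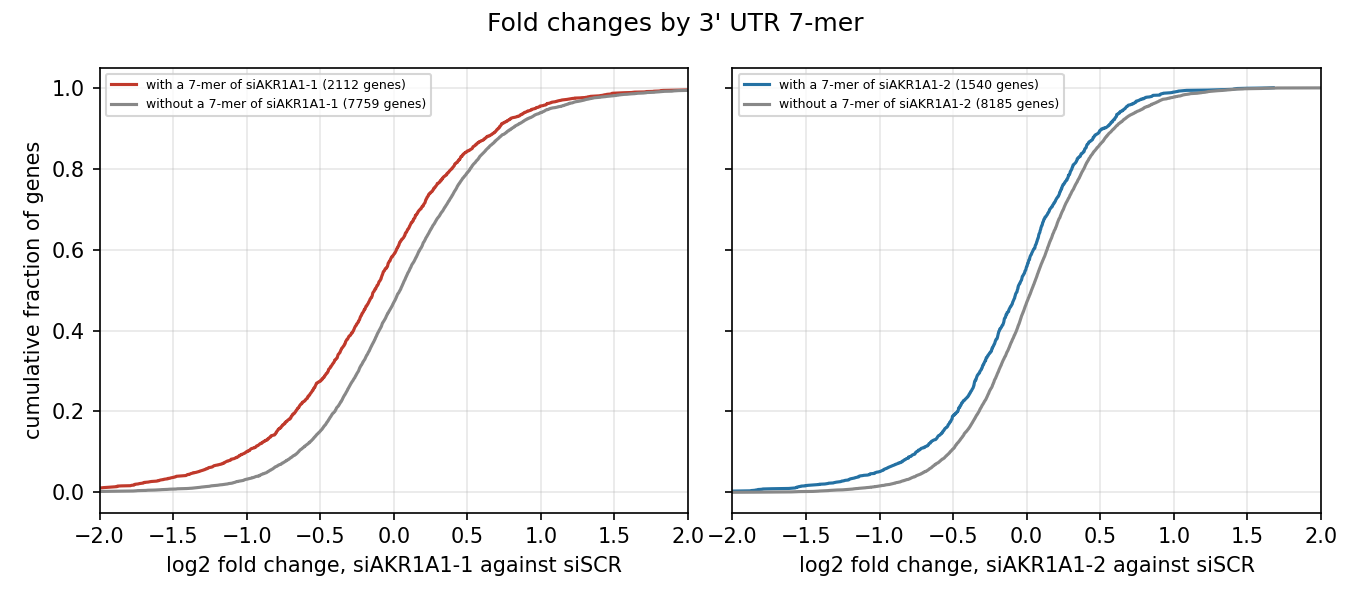
Cumulative fraction of genes (vertical axis) by log2 fold change against siSCR (horizontal axis). Genes are divided by whether the 3' UTR held a 7-mer of the pair chosen for that siRNA. Values beyond the plotted range are not drawn. The curve of genes with a 7-mer lies to the left, with a median of -0.14 for siAKR1A1-1 and -0.06 for siAKR1A1-2 over the genes tested in every comparison.

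TTN rose with both siRNAs (5.07-fold with siAKR1A1-1 and 3.10-fold with siAKR1A1-2). So did HEG1 (3.27 and 2.45-fold), the kinase DAPK3 (4.25 and 2.48-fold) and DUSP8, a phosphatase of MAP kinases (4.12 and 2.46-fold). ABCA1, the exporter of cellular cholesterol, went from 91.0 ± 18.3 (SD, n = 4) to 259 ± 25.7 (n = 3) and 211 ± 12.1 (n = 4), and PIEZO1, a mechanically gated ion channel, from 68.4 ± 11.5 to 165 ± 36.4 and 162 ± 29.7. Genes that fell with both siRNAs included KRR1, a ribosome assembly factor (2.65 and 3.00-fold), CYP1A1 (6.48 and 2.43-fold), SRM (2.48 and 2.22-fold), the metallothionein MT1G (3.04 and 2.20-fold), and FAH, an enzyme of tyrosine breakdown (2.23 and 2.71-fold). PTMA, prothymosin alpha, fell from 12796 ± 868 to 4397 ± 756 and 5974 ± 1133. SFN, a 14-3-3 protein, fell 2.92 and 2.02-fold. Adjusted p for these genes was at most 5.67e-04 in either comparison. PTMA, MT1G, TUBA1A and the ribosomal protein genes have closely similar copies in the genome, so their reads are uncertain. The lists called in both comparisons were ribosome biogenesis, heat shock, DNA replication and ribosomal proteins, all lower, and cholesterol synthesis, YAP and TEAD targets, cytoskeleton genes and mitochondrial transcripts, all higher. With an estimated correlation none was called in both, since 2 lists were called with siAKR1A1-1 and 0 with siAKR1A1-2. Lists called independently would share 2.17 of the 42 tested in both. Simulated unchanged groups against the same siSCR libraries shared at most 2 (mean 0.330 over 100 draws). These groups had a median of 1 list called in each comparison, so they had few lists to share. With the siSCR libraries split so that the comparisons shared none, 5 to 8 lists were called in both in the same direction (median 7.50 over 6 splits).

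Of 10211 genes tested against siSCR with both siRNAs, 1436 changed in the same direction, 673 higher and 763 lower, and 166 changed in opposite directions. The count in the same direction was 659 with a fold of at least 1.5 in both comparisons and 726 with an adjusted p under 0.01, and 943 without genes that carry the 7-mers or were not searched. Lists that overlap independently would share 245 higher and 282 lower genes. Simulated unchanged groups against the same siSCR libraries shared a median of 0 genes over 100 draws. Unchanged groups have few called genes to share, so this gives no level for groups with unrelated real changes, which were not simulated. Across genes, which are not independent replicates, the log2 fold changes had a Pearson correlation of 0.469 and a Spearman correlation of 0.486. The simulated groups had a mean Pearson correlation of 0.455. The covariance was 0.140 against a simulated mean of 0.0291, a difference of 0.111. The highest simulated Pearson correlation was 1, which separately drawn groups would not give, so these draws were not all independent. With independent noise in the simulated groups, the mean correlation was 0.463 and the mean covariance 0.0241. With the siSCR libraries split so that the comparisons shared none, a median of 864.5 genes changed in the same direction and the median correlation was 0.359 over 6 splits. In 52 of 100 splits of all libraries, the real one included, the correlation was at least as high.

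**Figure D4:**
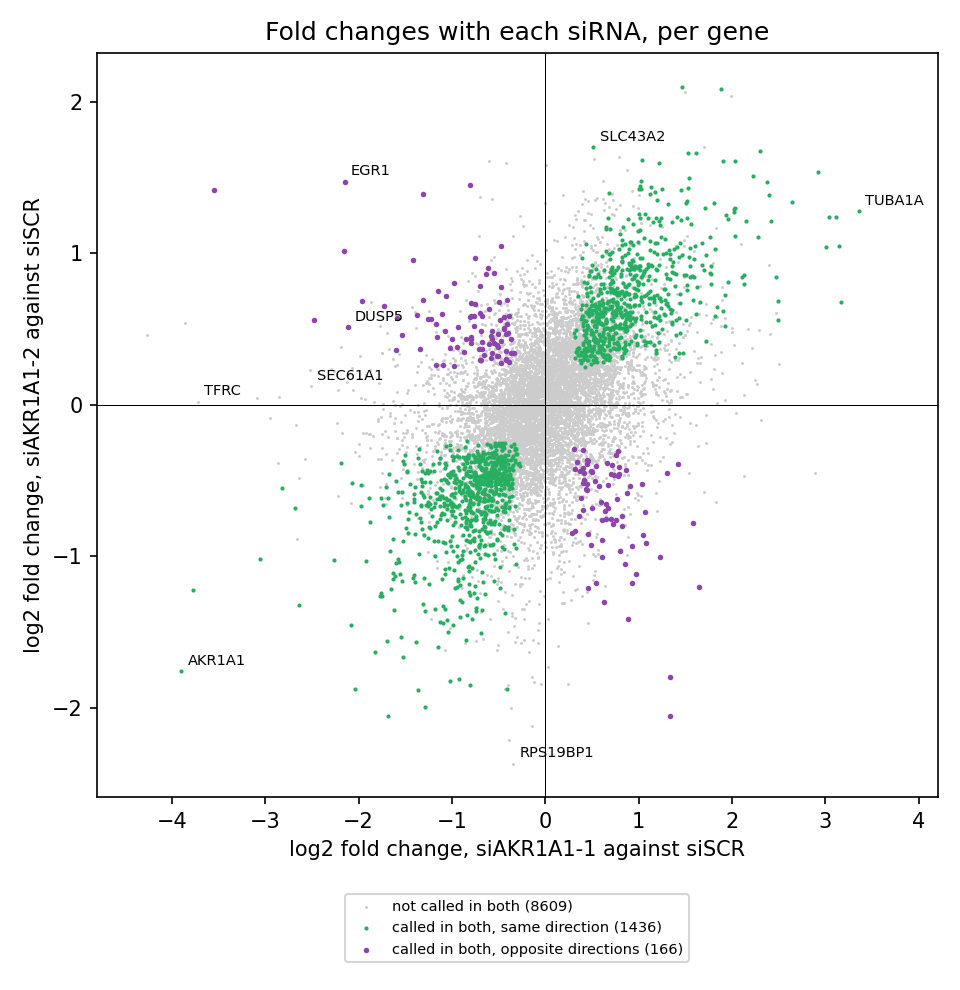
Log2 fold change of each gene against siSCR with siAKR1A1-1 (horizontal axis) and siAKR1A1-2 (vertical axis). Green points are the 1436 genes called in both comparisons in the same direction and purple points the 166 called in opposite directions, among them EGR1 and DUSP5.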

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

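The tests of the other strand of siAKR1A1-2, of the share of genes with the siSCR 7-mer, of shared changes without the 7-mers, and a condition on the number of 7-mers that pass for siSCR, were chosen after the results were seen. The correlation with split controls was planned, and the bound it was held to was chosen after.

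In 208 groups of library values of named genes and quality measures, 12 had a library far from the others, and chance gives about 1 in 20 groups. These groups are siSCR and siAKR1A1-2, since the 3 libraries of siAKR1A1-1 are too few for this test and were not screened. The gap of the extreme library over the range of its group was above the 95% critical value for APOH in siSCR (0.839), BRI3BP in siSCR (0.844), FEM1A in siSCR (0.893), ISG15 in siSCR (0.853), SEC61A1 in siSCR (0.836), SYT11 in siSCR (0.928), APOH in siAKR1A1-2 (0.894), CYFIP2 in siAKR1A1-2 (0.915), MBNL1 in siAKR1A1-2 (0.909), MT1G in siAKR1A1-2 (0.855), RPS28 in siAKR1A1-2 (0.906) and TFRC in siAKR1A1-2 (0.903). AKR1A1 was lower with siAKR1A1-1 than with siAKR1A1-2 by a log2 difference of -2.14. Genes that moved in opposite directions with the siRNAs, with a direct test past the threshold, had log2 differences (siAKR1A1-1 minus siAKR1A1-2) as follows: AKR1C1 (-1.83), CALR (-1.28), DUSP5 (-2.62), EGR1 (-3.62), MAFF (-2.26), MAP1LC3B (-1.52), NDRG1 (-1.90), NQO1 (-1.26), SLC7A11 (-1.97) and SLC7A5 (1.78).

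The 7-mer CTGAGAT in the 3' UTR went with lower values with siAKR1A1-1 than with siAKR1A1-2 across genes (log2 effect -0.303). Its z of -16.9 lies beyond the largest size in the permuted scans, 5.38, and the 7-mer occurs in 9 of 14 AKR1A1 transcripts, while the next strongest, TGAGATA (z -15.7), occurs in 1. This met the criterion set before the scan and is consistent with repression of further messages by the seed of siAKR1A1-1, but the match to AKR1A1 alone is weak evidence, because 16.1% of all 7-mers occur in an AKR1A1 transcript and the siRNA sequence is not given in the sources used here. A larger loss of AKR1A1 as the whole cause is argued against, since genes chosen as lower with siAKR1A1-1 had a median log2 fold change of 0.128 in siAKR1A1-2 libraries not used to choose them (range 0.0527 to 0.161 over 6 splits). A part of the pattern that depends on the AKR1A1 level stays open and was not tested.

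The 7-mer CAGTTAC went with lower values with siAKR1A1-2 across genes (log2 effect 0.221 for siAKR1A1-1 minus siAKR1A1-2), with a z of 10.2. The criterion set before the scan required the 7-mer in an AKR1A1 transcript, and both it and the next strongest, AGTTACA, are in 0 of 14, which argues against a seed in the strand that pairs with AKR1A1. GTAACTG, the reverse complement of CAGTTAC, occurs in 5 transcripts, and that of AGTTACA in 0, and the strand that carries the AKR1A1 sequence may repress messages. That test was chosen after the scan and cannot be told apart from a coincidence, by the same share of 16.1% of all 7-mers. AKR1A1 was lower with siAKR1A1-1, where CAGTTAC and AGTTACA went with log2 effects of -0.00680 and -0.0345 (z -0.294 and -1.53). With siAKR1A1-2 the effects were -0.228 and -0.233 (z -13.5 and -14.2). Against siSCR alone they were also the 2 strongest falling 7-mers with siAKR1A1-2. This argues against the loss of AKR1A1 for the part of the falls that goes with these 7-mers. For other genes lower with siAKR1A1-2 that loss stays among the open explanations, as untested.

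The siRNAs share 1436 genes changed in the same direction. Matches of the 4 7-mers in 3' UTRs are not the whole cause, since genes without them also changed. Of these genes 14.6% (977 of 6697) changed in the same direction with both siRNAs, against 14.1% of all genes. These calls were adjusted over all genes tested, while the 943 shared genes given for this removal were adjusted over the genes left. The 7-mers were chosen for a difference between the siRNAs, which made a lower share unlikely. The test therefore cannot decide on seed matches common to both siRNAs. Shared controls alone are argued against, since split controls left a correlation of 0.359. So is siSCR replicate 4, without which 1526 genes were shared. A seed of the siSCR siRNA stays open: the strongest rising 7-mer, TTTGCAC, met the criterion set beforehand with a z of 6.08 against 5.24 in permuted scans, but by a condition added after the scan was seen it cannot be told apart from other sources, since 8 7-mers passed, among them CCCCGCC at 5.95. It is in 21.8% of the genes higher with both siRNAs and 14.2% of all genes, so it does not account for most of them. A shared effect of the loss of AKR1A1 stays among the open explanations, as untested. At the falling end of the same scan, of the mean of both fold changes, 7-mers outside the 4 lay further beyond the permuted scans. Examples are GCCTGTA (z -9.60) and GTAATCC (z -9.49, with -8.58 for siAKR1A1-1 and -7.45 for siAKR1A1-2 against siSCR). The source of these shared falls was not tested.

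Other splits of the libraries into groups of the same sizes were run for each count. For siAKR1A1-1 against siSCR, 1 of 35 splits, the real one, called 3736 genes and the highest other called 0, which met the criterion set before. With 35 splits, the real one standing alone is the strongest outcome this test can give. The other splits mix libraries of both groups, which widens the spread within each, so few calls were likely in them. For lists, 2 of 35 splits called at least as many as the real 11, the highest other 12. Chance is therefore not excluded for the number of lists. For siAKR1A1-2 against siSCR the real split alone (1 of 35) reached 2959 genes (highest other 0). Between the siRNAs it alone reached 3289 genes (highest other 0). Both counts met the criterion set before, with the same limits. For siAKR1A1-2 the real split alone (1 of 35) also reached 17 lists, which met the criterion set before. Another split called 13 lists, and with an estimated correlation the real split called 0. This test therefore does not show that single lists hold. Of 100 splits of all libraries, 1 gave as many shared genes (real 1436, highest other 0). In 52 the correlation of fold changes was as high (real 0.469, highest other 0.822), so chance is not excluded for it. But this test cannot decide on the correlation, because a shared control group alone gives one. Simulated unchanged groups had a mean of 0.455, and with split controls the median was 0.359.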

How the results depend on the processing

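Voom on recovered reads, TMM scaling, scaling to library totals, the removal of genes with the 7-mers, split controls for lists, the removal of the 2 libraries apart on the third component and the comparison with the authors' deposited test were chosen after seeing the data. Leaving out each library in turn changed no direction and no call of AKR1A1 and moved no count by over 1.5 times: AKR1A1 log2 fold changes were -4.03 to -3.66 with siAKR1A1-1 and -1.86 to -1.60 with siAKR1A1-2, called genes 3016 to 3835, 2293 to 3097 and, between the siRNAs, 2786 to 3113, shared genes 1058 to 1526, their correlation 0.440 to 0.504, and called lists 10 to 13 and 14 to 17. With an adjusted p under 0.01 the counts were 2356, 1687 and 2156 genes and 726 shared, and with a fold of at least 1.5 they were 1539 for siAKR1A1-2, 2102 between the siRNAs and 659 shared, fewer because these thresholds are stricter. Without genes that carry the 7-mers or were not searched, 2285 genes changed with siAKR1A1-1, 1914 with siAKR1A1-2 and 1854 between the siRNAs, with 943 shared, of fewer genes tested. With split controls, of fewer libraries per fit, 864.5 genes were shared and the correlation was 0.359. Camera with an estimated correlation called 2 lists with siAKR1A1-1 and 0 with siAKR1A1-2. Limma's fry, which does not compare a list with other genes, called 24 with siAKR1A1-1, 25 with siAKR1A1-2 and 25 between the siRNAs. Without both siSCR replicate 4 and siAKR1A1-1 replicate 3, 3531, 3097 and, between the siRNAs, 2786 genes and 1417 shared genes were called. The replicate numbers did not pair the libraries: 2 of 10 pairs with the same number had deviations correlated over 0.1 (-0.397 to 0.231), and 2 correlated best with their own number. With the replicate block the counts were 3083, 2674 and 3042 genes, 1185 shared, and 10 and 17 lists, the NRF2 list no longer called with siAKR1A1-1. Of 366 results for named genes under the alternatives, 6501 of 6636 values stayed on their side of the threshold, 135 did not, and 0 reversed. Scaled to library totals, 2162 genes were higher and 1611 lower with siAKR1A1-1, 1568 and 1350 with siAKR1A1-2, and 1839 and 1477 between the siRNAs, so which side is larger depends on the scaling. The planned count models were not run, although whole reads could be recovered, and limma's voom was run on those reads in their place. Relative log expression is the scaling of the deposited values. In simulated libraries of this depth, with the same spread for all genes, the test recovered 47.8% of 1.5-fold changes with siAKR1A1-1. This limits the detection of smaller ones.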

Other observations

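The lists and the gene test of this part were chosen before the data were examined, and the pairing of genes with opposite or unequal changes and the removal of genes with the 7-mers were picked after their values were seen.

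Glycolysis genes fell in 6 of 20 cases with siAKR1A1-1 and rose in 2, 7 lower when adjusted over the list alone, and the list was not called (camera adjusted p = 0.193). ALDOA, an aldolase, fell 2.00-fold, from 1968 ± 307 (SD, n = 4) to 984 ± 48.8 (n = 3), PKM, a pyruvate kinase, 1.61-fold and PFKFB3, a regulator of glycolytic flux, 2.34-fold. With siAKR1A1-2 these genes were at 2016 ± 126, 4539 ± 505 and 149 ± 9.35 (n = 4), and the direct differences had adjusted p of at most 1.12e-05. The peroxiredoxin PRDX1 fell 1.94-fold with siAKR1A1-1, from 4689.6 ± 402 to 2417 ± 144, and was at 4682 ± 418 with siAKR1A1-2. In the glucuronate and ascorbate pathway, to which AKR1A1 belongs, 2 of 10 genes fell and 2 rose with siAKR1A1-1 (camera adjusted p = 0.973), and 2 fell with siAKR1A1-2 (camera adjusted p = 0.792).

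NR0B2, a nuclear receptor that represses bile acid synthesis, fell from 80.3 ± 11.8 (SD, n = 4) to 5.40 ± 2.81 with siAKR1A1-1 (n = 3, log2 fold change -3.77, adjusted p = 1.67e-07) and 34.2 ± 6.98 with siAKR1A1-2 (n = 4, log2 fold change -1.22, adjusted p = 8.75e-05). In its list of bile acid genes 3 of 7 fell and 1 rose with siAKR1A1-1, and the list was not called (camera adjusted p = 0.274). GBP1, an interferon-induced GTPase, rose 4.76-fold with siAKR1A1-1 and ISG15 2.04-fold, in a list of which 4 of 14 genes rose and 3 fell (camera adjusted p = 0.193). Without genes that carry the 7-mers or were not searched, this list had an adjusted p of 0.0260, and adjusted p = 0.171 with an estimated correlation. In that setting the urea cycle (adjusted p = 0.0175, and adjusted p = 0.196 with an estimated correlation) and nuclear oxidative phosphorylation lists (adjusted p = 0.0260, and adjusted p = 0.481 with an estimated correlation) were also called lower with siAKR1A1-1 at the preset correlation. So was the fatty acid synthesis list, higher with siAKR1A1-2 (adjusted p = 0.0274, and adjusted p = 0.166 with an estimated correlation). In the direct comparison the oxidative phosphorylation list was lower with siAKR1A1-1 (adjusted p = 0.0399, and adjusted p = 0.501 with an estimated correlation) and YAP and TEAD targets higher (adjusted p = 0.00942, and adjusted p = 0.154 with an estimated correlation). With an estimated correlation 0 lists were called in that setting in any comparison. SLC40A1, the iron exporter ferroportin, rose 2.71-fold with siAKR1A1-1 and 1.59-fold with siAKR1A1-2, in an iron and ferroptosis list of which 4 of 18 genes rose and 8 fell with siAKR1A1-1 (camera adjusted p = 0.545) and 7 rose and 3 fell with siAKR1A1-2 (camera adjusted p = 0.303). The collagen genes COL1A2 and COL1A1, markers of mesenchymal cells, rose 2.50 and 1.76-fold with siAKR1A1-1 and 1.76 and 1.55-fold with siAKR1A1-2. APOC3 and APOH, which encode plasma apolipoproteins, rose 2.57 and 2.17-fold with siAKR1A1-1 and 1.46 and 1.33-fold with siAKR1A1-2. APOA2, a more abundant apolipoprotein transcript, fell 1.58-fold with siAKR1A1-1, from 13252 ± 1140 to 8394 ± 597 (adjusted p = 2.23e-04), and was at 13398 ± 1046 with siAKR1A1-2. Their list of lipoprotein genes was not called with either siRNA: 5 of 17 rose and 2 fell with siAKR1A1-1 (camera adjusted p = 0.199), and 6 rose and 1 fell with siAKR1A1-2 (camera adjusted p = 0.0723).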
